A study of Mus musculus with 8 samples.

How the data were processed

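RNA abundance was measured on 8 single-colour (Cy3) Agilent 60-mer microarrays, 2 for each of 4 groups: cells of the mouse pre-B line 1676 with a control vector or with a vector for hsa-miR-125b, kept in IL-7 or for 24 h without it. Per the labels, cells grew in medium with 7.5% FCS, transduced cells were selected with 1 µg/ml puromycin, and 100 ng of total RNA was labelled per sample. No values of other series are among the files (0 columns).

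The scanner files hold, per the file headers, a processed signal as an intensity on a linear scale: spatially detrended, background-subtracted spot signal, with surrogate values where a spot is not above background, and not normalized between arrays. Per the file headers they also hold the mean signal and the median local background of each spot as an unprocessed intensity, and quality marks per spot of another kind (other: 0 or 1 for well above background, saturated or not uniform). The headers name Agilent Feature Extraction 10.7.3.1 for the arrays with IL-7 and 10.7.1.1 for those without, whereas the submitters' processing notes name 10.7.1.1 for all. The authors also deposited a table of intensity values for 55821 probes, 140 of them controls, on a linear scale. Its columns share the same distribution (median 21.7 in each), as quantile normalization gives, and its log2 values correlate across probes with the scanner signal of the same array at r of at least 0.999.

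The scanner's processed signal was used, not the deposited table. Of 62976 spots, 3671 control spots were left out, and the spots of a probe were averaged, which gave 55681 probes. A further 58 probes, with every spot marked as not uniform on at least 1 array, were dropped. Values were log2 signal minus the array's own log2 75th percentile. A probe was kept if it was well above background on both arrays of at least 1 group (29811 probes), and each gene name was represented by the kept probe with the highest mean over the 8 arrays. That left 20677 genes, 12613 of them with a gene symbol. Names were brought up to date from a table of RefSeq accessions and symbols: 27235 probes by accession, 3581 by symbol and 565 by synonym, while 24300 kept the name in the files. The names of 14.3% of spots differ between the versions of the array grid used for the 2 slides. Probe positions are those of the files, in mm9.

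Differences were tested with limma 3.58.1 (lmFit and eBayes) under R 4.3.3, with version 1.17.8 of the data.table package, in a model with a mean for each of the 4 groups over all 8 arrays, with 4 residual degrees of freedom. The prior had 1.82 degrees of freedom and an SD of 0.11 on the log2 scale. The 6 comparisons were miR-125b against control with IL-7, the same without IL-7, their average, withdrawal of IL-7 in control cells, withdrawal in miR-125b cells, and the difference of the withdrawal response between these cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of that comparison. All p are two-sided. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and each group holds n = 2 arrays. The number of arrays limits the precision: in simulated data with 200 changed genes among 20677, 2-fold changes were found in 50.7% and 68.7% of cases for miR-125b with and without IL-7, 59.7% for withdrawal in each cell type, 29.9% for the difference and 73.1% for the average. Between 5 and 12 unchanged genes were called there, and 0 changed genes with the wrong sign. In the data far more genes were called: 54.2% and 52.4% on withdrawal in control and miR-125b cells, and 15.8% in the average. The adjusted threshold then admits larger p, so the simulated shares are not the recovery for these comparisons.

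Where a probe was well above background on no array of a group, its fold change is given only as a bound ("at least"), measured from the higher of the probe's own signal and the lowest signal well above background on each dim array. No fold is given where the probe was dim in both groups. Where it was well above background on 1 of the 2 arrays, the fitted fold is given with that number and is less certain, since the dim array enters the mean. These statements concern the probe that represents the gene.

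In all, 20 gene lists were fixed before the data were examined: published miR-125b targets; STAT5 and IL-7 signalling targets; FOXO targets; late pre-B and immature B differentiation; the pro-B, pre-BCR and early B programme; pro-apoptotic and pro-survival BCL2 family members; p53 targets; cell cycle; MYC targets and ribosome biogenesis; glycolysis; cholesterol synthesis; the JNK and MAP3K pathway; NF-kappaB targets; interferon response; and markers of myeloid, T and NK, erythroid, plasma and stromal cells. Each was tested in each comparison against the other genes with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg over the 120 tests. With the correlation estimated from the list instead, 0 of the 120 passed (lowest camera adjusted p = 0.599), so every list call below rests on the preset value. That form of camera has only the 4 residual degrees of freedom of the fit, so hardly any list could pass over 120 tests. For JNK genes in miR-125b against control without IL-7 the estimate was −0.0456, below the preset value. Even so, their unadjusted camera p rose from 0.0454 to 0.0994. These adjusted p alone therefore do not tell whether correlation between genes explains a call. The estimates were far above the preset value for MYC targets and ribosome biogenesis (0.856), glycolysis (0.649), cell cycle (0.405) and pro-survival genes (0.368). So they were for FOXO (0.363), late pre-B (0.337), NF-kappaB (0.268) and cholesterol genes (0.166). They were nearer to it for published targets (0.018), early B genes (0.0227) and p53 targets (0.0596). Where the estimate is high, the camera p at the preset value may be much too small. Limma's fry, which asks whether a list's genes move on balance in either direction without comparing them with other genes, was run beside camera. Its value is given below only where camera passed and fry did not. Of 20 lists, fry passed 6 and 9 for miR-125b with and without IL-7 and 11 for the average. It passed 14 and 11 for withdrawal in control and miR-125b cells and 0 for the difference. Camera passed 5, 8, 8, 8, 6 and 2. JNK genes passed fry but not camera for miR-125b (fry adjusted p = 0.00327 with IL-7 and 0.000905 without). The target list was written from general knowledge of miR-125b, which may rest in part on work with these samples (Map3k11 among them), and is not fully independent evidence of its direction.

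The genes named were set by a rule before the data were examined: per comparison, the 10 highest and 10 lowest fold changes among called genes with a symbol, changed the same way in both same-numbered array pairs; up to 6 called members per list; and always Map3k11, Bak1, Bmf, Bbc3, Bcl2l11, Trp53, Irf4, Prdm1, Rag1, Rag2, Cish, Il7r, Bcl2, Ccnd3, Myc, Blnk and Lat. Where 0 genes were called, the 5 with the lowest p are named. Genes named outside this rule are said to be so. Of the genes this rule takes, 3 are not reported here by name. They stay in the counts and list tests but are left out of the values by gene under other settings.

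Equal replicate numbers were not taken to pair arrays. A fit with replicate number as a block was run as an alternative. The arrays with IL-7 lie on 1 slide and those without on another, so the slide cannot be separated from withdrawal. Other alternatives, all planned, were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter on dim probes, a filter asking for all 8 arrays, the mean of a gene's probes, the deposited table, the 4 arrays compared alone, a mean-variance trend with robust eBayes, a 2-fold threshold, an estimated correlation for camera, and leaving out each array. A planned test of miR-125b seed sites in 3′ untranslated regions was not run, since the sequences were not at hand. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.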

Results

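Gene expression was measured in 1676 cells, a mouse pre-B cell line without the adaptor proteins SLP-65 and LAT that is grown in interleukin-7 (IL-7). The cells carried a control vector or a vector for the human microRNA miR-125b, and were kept in IL-7 or cultured without it for 24 h, which the labels give as a way to induce differentiation. Each of the 4 groups held 2 arrays. On each array 26587 to 30522 of 55681 probes (47.8% to 54.8%) were well above background, with the fewest on control without IL-7 replicate 1, and 0 spots were saturated. The 75th percentile of the signal was 325 to 379 on the arrays with IL-7 and 606 to 722.5 on those without. Replicates correlated across genes at r = 0.994 to 0.996, and the SD of their log2 difference was 0.32 to 0.42. All 4 arrays with IL-7 lay on 1 slide with 1 scan and all 4 without IL-7 on another, so the vectors were compared within a slide, while withdrawal cannot be told apart from slide and scan. On each slide the control arrays lay in columns 1 or 2 and the miR-125b arrays in columns 3 or 4, so vector cannot be told apart from position on the slide.

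**Figure D1:**
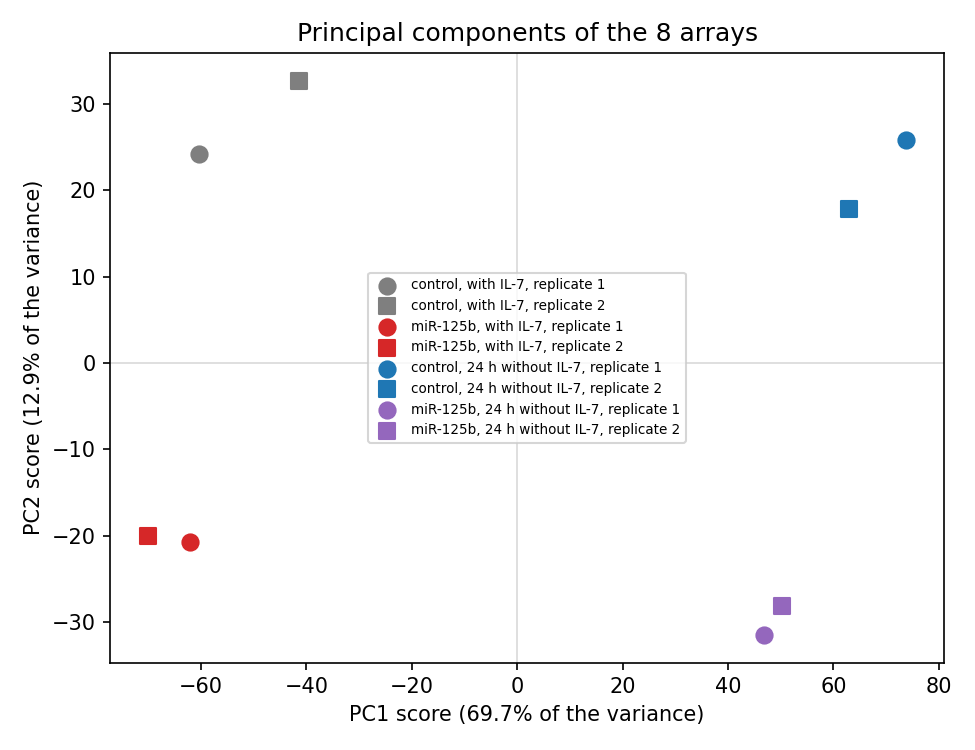
Scores of the 8 arrays on principal components 1 (69.7% of the variance) and 2 (12.9%) over 20677 genes, with colours for the groups, circles for replicate 1 and squares for replicate 2. The arrays with and without IL-7, which are also the 2 slides, part along component 1, and the control and miR-125b arrays part along component 2.

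Whether miR-125b changes the mRNAs of growing pre-B cells was asked in the cells kept in IL-7. Of its published targets, Trp53inp1, a stress protein induced by p53, fell by 1.60 on the log2 scale (SE 0.09, adjusted p = 0.0123), Abtb1 by −1.23 and Arid3a, a B-lineage transcription factor, by −1.22. Map3k11, a kinase upstream of JNK measured by a probe on chromosome 19 from 5702495 to 5702554, went from a mean of 1.89 (SD 0.01, n = 2) in control cells to 1.08 (SD 0.08, n = 2), a change of −0.80 (SE 0.07, adjusted p = 0.0206). Il7r, the receptor subunit for IL-7, fell by 0.66 (SE 0.09, adjusted p = 0.0363). The growth factor gene Tgfb3 rose by 4.48 (SE 0.41) and its neighbour Ift43, a component of ciliary transport, by 3.53 (SE 0.36). Both miR-125b arrays lay on the same side of both control arrays for each of these genes, as is likely for genes named because they were called.

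In this comparison 538 of 20677 genes were called, 233 higher and 305 lower with miR-125b, 187 of them by at least 2-fold. The other genes at the top had probes that were not well above background in control cells, so that only bounds can be given. Fndc4 was at least 6.58-fold higher, Ly86, a partner of a Toll-like receptor relative on B cells, at least 5.75-fold, Sgsm1 at least 4.15-fold, Nol4l at least 3.72-fold, Syngr1 at least 3.33-fold, Tro at least 2.45-fold, Phactr2 at least 2.39-fold and the laminin gene Lamb1 at least 2.20-fold. Among the lowest, the elongation factor gene Ell3 was measured on all arrays and fell by 2.26 (SE 0.12). Pdx1 was at least 2.95-fold lower, Shank2 at least 2.67-fold, the fatty acid receptor gene Ffar2 at least 2.01-fold, Pdgfa at least 1.43-fold, Scarletltr at least 1.31-fold, Gsg1l at least 1.28-fold and Prl3a1 at least 1.05-fold. Mxra7 and Slc39a5 were also called lower, but their probes were not well above background in either group. Of the BCL2 family, Bak1 (−0.34, adjusted p = 0.0972), Bmf (−0.54, adjusted p = 0.206), Bbc3 (0.15), Bcl2l11 (−0.14) and Bcl2 (−0.29) did not pass. Neither did Myc (0.80, adjusted p = 0.157), Rag1 (0.90), Rag2 (1.28, adjusted p = 0.0683), Trp53 (0.31), Irf4 (0.15), Prdm1 (0.20), Cish (0.67) or Ccnd3 (−0.01).

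Of 34 measured published targets of miR-125b, 7 fell, 1 rose and 26 did not pass, and 10 fell and 1 rose when adjusted over the list alone; the list was drawn from general knowledge and is not fully independent evidence of their direction. Besides those above, Traf6, an adaptor of Toll-like receptor signalling, fell by 0.69, although its 3 probes ranged from −0.69 to 0.30, and the cytokine receptor gene Lifr was at least 1.14-fold higher. As a list the targets were lower than other genes (camera adjusted p = 0.00186; adjusted p = 0.599 with an estimated correlation). The 18 MYC targets and ribosome biogenesis genes, the 15 of glycolysis and the 16 of cholesterol synthesis were each higher as a list. Their camera adjusted p were 1.47e-06, 0.000286 and 5.56e-05 (each adjusted p = 0.599 with an estimated correlation). The first list is called ribosome biogenesis below, though not all its members belong to that process, such as the spermidine synthase gene Srm. No single member passed over all genes in these 3 lists, and 0, 3 and 8 rose when adjusted over the list alone. The 28 cell cycle genes were lower as a list (camera adjusted p = 0.0108; adjusted p = 0.642 with an estimated correlation), with the cyclin gene Ccne1 (−0.71) as the 1 member that fell, and also 1 when adjusted over the list alone. Limma's fry did not pass for ribosome biogenesis, glycolysis and the cell cycle (adjusted p = 0.124, 0.134 and 0.0825).

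The other 15 lists did not pass with IL-7, at camera adjusted p from 0.0576 for pro-survival BCL2 family genes to 0.936 for late pre-B genes. Within them, Fas (−1.04) and the growth inhibitor Btg2 (−0.96) fell with Trp53inp1 among 21 p53 targets, and the transcription factor gene Jun (−0.65) and the phosphatase gene Dusp1 (−0.63) fell with Map3k11 among 15 genes of the JNK pathway, whose median was 0.03 (−0.03 with normexp) and mean −0.13. The cytokine receptor gene Flt3 fell by 1.24 with Il7r among 20 early B genes, while its second probe read 0.36. Among 24 late pre-B genes Cr2 rose by 0.77 and Pou2af1, a B-cell coactivator, fell by 0.37. Adjusted over the list alone, 4 p53 targets fell and 2 rose, 4 JNK genes fell, 3 early B genes fell and 1 rose, and 2 late pre-B genes rose and 2 fell. The markers of myeloid, T and NK, erythroid, plasma and stromal cells and the interferon genes had 0 called members.

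The count with IL-7 was fragile. It was 0 with only the 4 arrays compared, 1 with no filter on dim probes, 915 with probes above background on all arrays and 1558 with a mean-variance trend. It was 0 without replicate 2 of either group with IL-7 (limma; 3342 and 3414 genes at an unadjusted p under 0.05), 26 or 28 without an array lacking IL-7, and 100 or 140 without replicate 1 of miR-125b or control cells, and scaling to the median gave 135 higher and 85 lower. Of 19 other settings, the calls of Map3k11 and Il7r were lost in 11 and 14, at adjusted p up to 0.169 and 0.207. Of 35 called genes of the naming rule, 35 lost their call in at least 1 setting and 27 in more than 50%, among them Tgfb3, Ift43, Fas and Traf6. The cell cycle list lost its call in 3 of 17, at adjusted p up to 0.123. Plasma cell markers gained a call in 2 (adjusted p down to 0.00815) and pro-survival and NF-kappaB genes in 1 each (0.0295 and 0.0227).

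**Figure D2:**
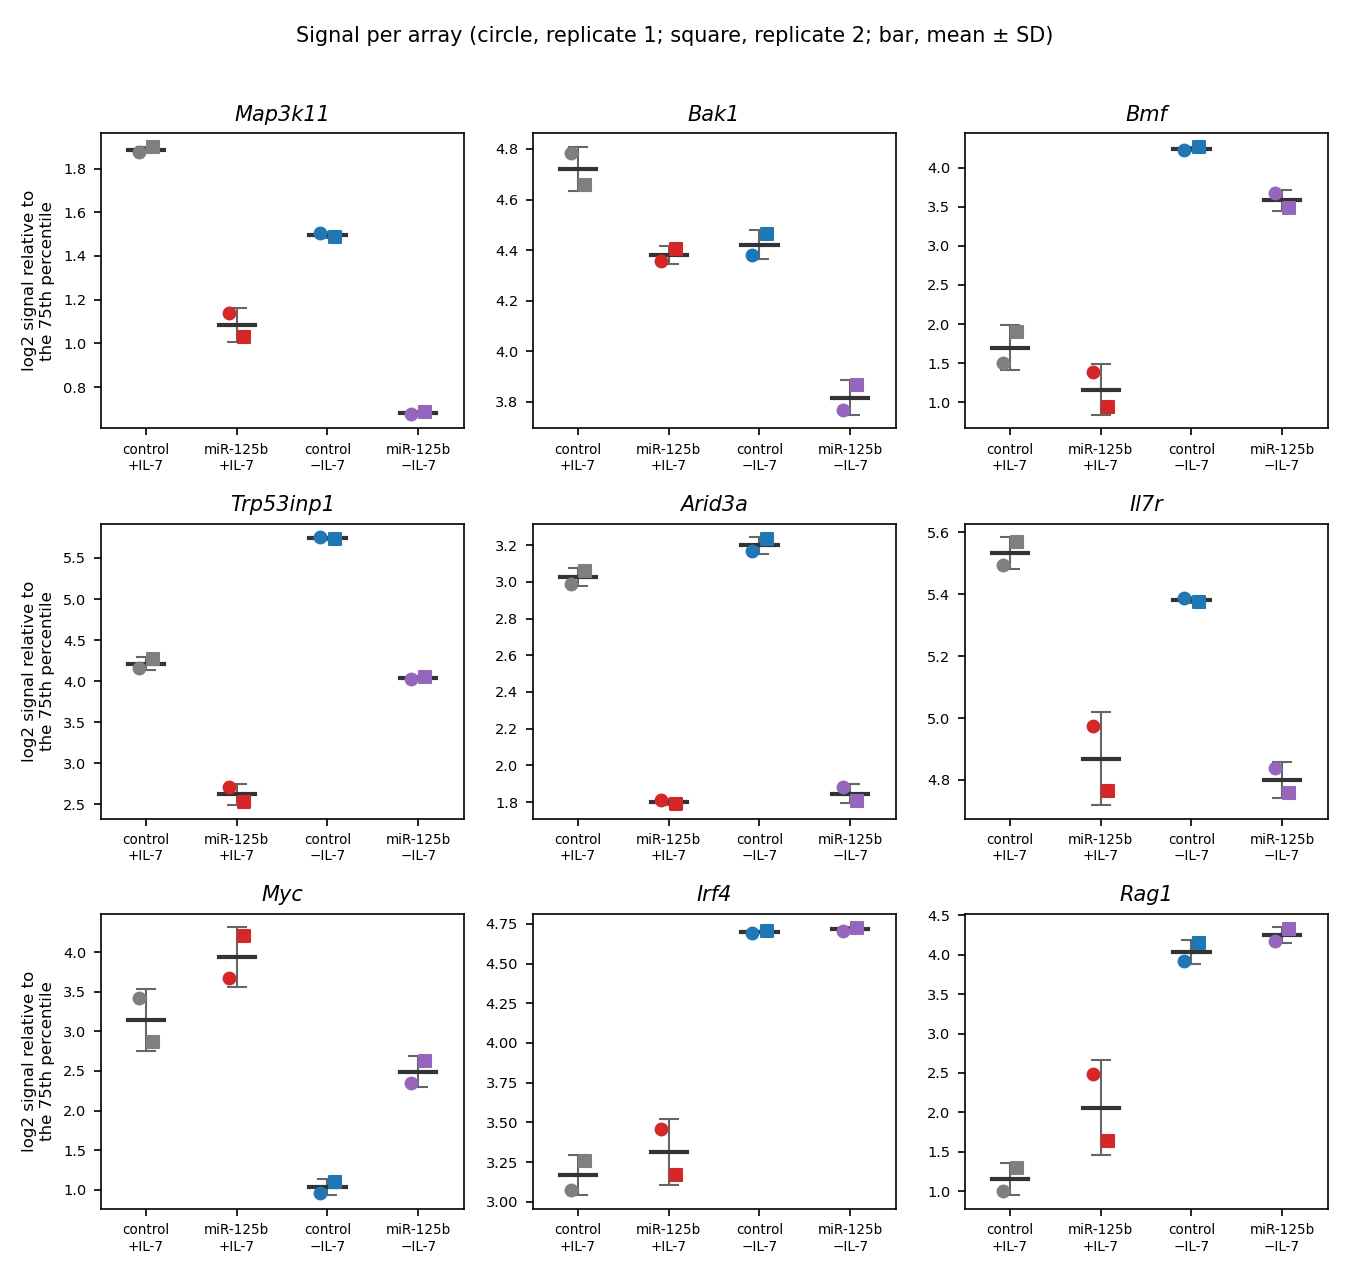
Log2 signal relative to the 75th percentile of the array for 9 genes in the 4 groups; circles are replicate 1, squares replicate 2, and bars the mean ± SD (n = 2). Map3k11, Trp53inp1, Arid3a and Il7r are lower in miR-125b cells in both IL-7 conditions, and Bmf, Irf4 and Rag1 are higher without IL-7 than with it.

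The same comparison in cells left without IL-7 for 24 h showed what miR-125b changes during withdrawal. Of the published targets, Trp53inp1 fell by 1.70 (SE 0.09), Arid3a by −1.35, Abtb1 by −1.12 and Map3k11 by −0.82 (SE 0.07, adjusted p = 0.00894). Bak1, an effector of mitochondrial apoptosis, fell by 0.61 (SE 0.08, adjusted p = 0.0202), and so did the NF-kappaB feedback inhibitor Tnfaip3 (−1.1, SE 0.18). Myc was 1.46 higher (SE 0.25, adjusted p = 0.0335), and the MHC class II chaperone gene Cd74 fell by 2.17 (SE 0.34, adjusted p = 0.0277). Il7r fell by 0.58 (adjusted p = 0.0299).

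Without IL-7, 1339 genes were called, 615 higher and 724 lower with miR-125b, 339 by at least 2-fold. Measured on all arrays at the top were Ift43 (3.96, SE 0.36), the sialyltransferase gene St3gal6 (2.76, SE 0.09) and Smim22 (2.69, SE 0.14), and at the bottom Ell3 (−2.79) and the B-lineage surface protein gene Ly6d (−2.70, SE 0.21). Tgfb3 (4.06, or 2.73 to 4.25 under other settings) and Lamb1 (3.63, or 2.14 to 4.02) were also at the top, but each was well above background on only 1 of the 2 control arrays, and each call was lost in 4 of 18 settings. As bounds, Klf3 was at least 6.55-fold higher, Septin12 at least 6.11-fold, Syngr1 at least 2.66-fold, Tro at least 2.48-fold and the Wnt receptor gene Fzd9 at least 2.12-fold. Ivl was at least 4.19-fold lower, Spata4 at least 3.47-fold, Tmem139 at least 3.46-fold, Cdk5r2 at least 2.82-fold, Evc at least 2.56-fold, Cemip at least 2.36-fold and the phospholipase gene Plcb1 at least 2.33-fold. Rnf150 was at least 1.96-fold lower at its chosen probe, but 0.93 higher on the log2 scale at the probe chosen with no filter on dim probes. Bmf (−0.66, adjusted p = 0.11), Bbc3 (−0.25), Bcl2l11 (−0.26), Bcl2 (−0.21), Trp53 (0.45), Irf4 (0.02), Prdm1 (0.18), Rag1 (0.21), Rag2 (0.63), Cish (−0.21) and Ccnd3 (0.12) did not pass.

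Of the 34 targets, 9 fell, 1 rose and 24 did not pass without IL-7, and 15 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000335; adjusted p = 0.599 with an estimated correlation). Traf6 fell by 0.88, with probes from −0.88 to −0.02, and S1pr1, a receptor for lymphocyte egress, rose by 0.88. Among 10 NF-kappaB targets, 5 fell (Relb by −1.13, with probes from −1.13 to −0.03, then Tnfaip3, Nfkb2 by −0.83, Nfkbia by −0.57 and Nfkbie by −0.48) and 5 did not pass; 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000506; adjusted p = 0.599 with an estimated correlation). Ribosome biogenesis was higher as a list (camera adjusted p = 1.1e-05), and in it the spermidine synthase gene Srm (1.66) and the RNA polymerase I gene Polr1b (1.34) rose. So were glycolysis (camera adjusted p = 0.00363), where hexokinase 2, Hk2, rose by 1.54, and cholesterol synthesis (camera adjusted p = 0.00106), where Fdps (0.55), Mvd (0.43) and Fdft1 (0.32, with its other probe at −0.59) rose. With an estimated correlation these had an adjusted p = 0.599, 0.613 and 0.599, and when adjusted over the list alone 7, 1 and 6 members rose. Limma's fry did not pass for ribosome biogenesis (adjusted p = 0.089) and glycolysis (adjusted p = 0.154).

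Late pre-B genes were lower as a list (camera adjusted p = 0.0456; adjusted p = 0.671 with an estimated correlation), with Cd74 and the MHC class II gene H2-Ab1 (−0.70) falling among 24, and 9 falling when adjusted over the list alone (fry adjusted p = 0.152). Early B genes were lower too (camera adjusted p = 0.0455; adjusted p = 0.599 with an estimated correlation), with Flt3 (−1.07, second probe 0.14) and Il7r falling among 20, and their median of −0.15 became 0.04 under scaling to the median, which moved all genes alike and left the list at −0.14 relative to them. Of 4 pro-survival BCL2 family genes Mcl1 fell by 0.62 (camera adjusted p = 0.0162; adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone, 4 early B genes fell and 1 rose, and 2 pro-survival genes fell. The other 12 lists did not pass, at camera adjusted p from 0.0796 for interferon genes, of which Irf7 (−1.096) and Isg15 (−0.46) fell, to 0.937 for myeloid markers. In them, the death agonists Bid (1.23) and Pmaip1 (0.61) rose and Bak1 fell, Jun (−1.07) and Dusp1 (−0.65) fell with Map3k11, Ccne1 (−1.08) fell and E2f1 (0.38) rose. Among STAT5 targets Ccnd2, measured on 1 of 2 miR-125b arrays (−1.71, with the call lost in 13 of 18 other settings), Socs3 (−0.76), Mcl1 and Pim2 (−0.46) fell. Btg2 (−0.88), Fas (−0.84), Ccng2 (−0.72) and Klrb1c (−0.59) fell, and Sesn1 rose by 0.49.

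This count was 496 with only the 4 arrays compared. It was 3, 30, 36 and 114 without miR-125b replicate 1, miR-125b replicate 2, control replicate 1 and control replicate 2 of the arrays lacking IL-7 and 875 without either control array with IL-7, and scaling to the median, which moved the median of all genes from −0.01 to 0.17, gave 671 higher and 187 lower. Of 19 other settings, the calls of Il7r, Bak1, Myc and Map3k11 were lost in 10, 8, 6 and 4, at adjusted p up to 0.157, 0.13, 0.17 and 0.0813. Of 60 called genes of the naming rule, 58 lost their call in at least 1 setting and 17 in more than 50%: Ccnd2, Ccng2, E2f1, Fas, Fdft1, Fzd9, H2-Ab1, Il7r, Irf7, Isg15, Ivl, Mvd, Nfkbia, Nfkbie, Pim2, Pmaip1 and Sesn1. The early B, late pre-B and pro-survival lists lost theirs in 12, 7 and 2 of 17 settings, at adjusted p up to 0.355, 0.305 and 0.14. Interferon genes gained a call in 2 (adjusted p down to 0.00893) and cell cycle genes in 1 (0.0277).

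Across genes, the effects of miR-125b with and without IL-7, which share no array, correlated at r = 0.553 (Spearman's rho = 0.565); genes are not independent replicates. Of the genes called in each, 382 were shared, 380 of them in the same direction; 167 shared genes were higher and 213 lower (independent lists would share 6.93 of the higher genes).

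Averaged over both IL-7 conditions, which places 4 arrays against 4, more genes were called than in either condition alone. Map3k11 was lower by −0.81 (SE 0.05, adjusted p = 0.00234), Bak1 by −0.47 (SE 0.06, adjusted p = 0.00858), Bmf, a BH3-only death agonist, by −0.60 (SE 0.14, adjusted p = 0.0406) and Il7r by −0.62 (SE 0.07, adjusted p = 0.0062). Myc was higher by 1.13 (SE 0.18, adjusted p = 0.0147) and the recombinase gene Rag2 by 0.96 (SE 0.18, adjusted p = 0.0245). Trp53inp1 (−1.65), Arid3a (−1.29) and Abtb1 (−1.18) fell most among the targets. Bbc3 (−0.05), Bcl2l11 (−0.20), Bcl2 (−0.25), Trp53 (0.38, adjusted p = 0.0705), Irf4 (0.08), Prdm1 (0.19), Rag1 (0.56), Cish (0.23) and Ccnd3 (0.06) did not pass. Blnk (0.13) and Lat (−0.16), the genes disrupted in this line, did not pass either, and their probes may lie outside the deleted part.

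In this average 3269 genes were called, 1500 higher and 1769 lower, 370 by at least 2-fold. Measured well above background in all groups were Ift43 (3.75, SE 0.26), Ell3 (−2.53, SE 0.09) and Ly6d (−2.15, SE 0.15), and Tgfb3 (4.27, SE 0.29) on all arrays but 1. The other names at the top, Lamb1, Tro, Sgsm1, Klf3, Nol4l, Fndc4, Syngr1 and Septin12, had probes not well above background in control cells of at least 1 IL-7 condition. The other names at the bottom, Spata4, Pdx1, Ffar2, Ivl, Aif1, Shank2, Dlx6 and Evc, had probes not well above background in miR-125b cells of at least 1 condition, and no average fold is given for these.

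Of the 34 targets, 12 fell, 1 rose and 21 did not pass, and 16 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.00199). Traf6 (−0.79) and Tnfaip3 (−0.75) were among them. Of 18 ribosome biogenesis genes 7 rose, such as Srm (1.31), Polr1b (1.09), Gnl3 (0.81) and Nop16 (0.57), and 16 when adjusted over the list alone (camera adjusted p = 8.96e-07). Of 15 glycolysis genes 6 rose, such as Hk2 (1.35), Aldoa (0.61) and Tpi1 (0.43), and 8 when adjusted over the list alone (camera adjusted p = 0.000335). Of 16 cholesterol genes 8 rose, such as Fdps (0.46), Mvd (0.42) and Lss (0.39), and 9 when adjusted over the list alone (camera adjusted p = 0.000103). Of 10 NF-kappaB targets 6 fell, such as Relb (−0.78), Nfkb2 (−0.52) and Traf1 (−0.52), while the adhesion gene Icam1 rose by 0.44, and 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00504). For each of these 5 lists the adjusted p = 0.599 with an estimated correlation, and fry did not pass for glycolysis (adjusted p = 0.0647). Pro-survival BCL2 genes were lower (camera adjusted p = 0.0219; adjusted p = 0.599 with an estimated correlation), with Mcl1 (−0.48) and Bcl2l2 (−0.32) falling among 4, and 3 when adjusted over the list alone.

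Early B genes were lower as a list (camera adjusted p = 0.0456; adjusted p = 0.599 with an estimated correlation): Flt3, Il7r and Bach2 (−0.48) fell and the DNA polymerase gene Dntt (0.68) rose among 20, with the same counts when adjusted over the list alone. Cell cycle genes were lower (camera adjusted p = 0.0455; adjusted p = 0.706 with an estimated correlation, fry adjusted p = 0.0515), with 5 of 28 falling, such as Ccne1 (−0.90), Cenpe (−0.32) and Rrm2 (−0.28), and E2f1 (0.23) rising, and 10 falling and 2 rising when adjusted over the list alone. Their median of −0.14 became 0.00 under scaling to the median, which left the list at −0.12 relative to all genes. The other 12 lists did not pass, at camera adjusted p from 0.137 for plasma cell markers, of which Xbp1 (0.41) rose, to 0.875 for pro-apoptotic BCL2 genes, of which Bid (0.99) and Pmaip1 (0.54) rose and Bak1 and Bmf fell. Among them, 6 late pre-B genes fell, such as Cd74 (−1.26) and Il2ra (−1.16), and 2 rose, 3 interferon genes and 3 JNK genes fell, and of 10 myeloid markers 0 passed, with a median of −0.03 and a mean of 0.06. Adjusted over the list alone these counts were the same. FOXO targets rose and fell 4 to 4, STAT5 targets 3 to 5 and p53 targets 2 to 4, or 6 to 8, 3 to 7 and 3 to 5 when adjusted over the list alone. The pro-apoptotic genes had a median of −0.08 and a mean of 0.03, and T and NK markers, 1 higher and 2 lower, −0.17 and 0.06. Of 4 erythroid markers Epor (0.82) rose, and of 2 stromal markers 0 passed. Of 34 ways of splitting the arrays 4 and 4, 3, the real one among them, put 8 or more lists past the threshold, so chance is not excluded for the number of lists.

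The averaged count was 995, 1487, 1173 and 1279 without control replicates 1 and 2 and miR-125b replicates 1 and 2 lacking IL-7, and 1707 and 2018 without replicate 2 of control or miR-125b cells with IL-7. Scaling to the median moved the median of all genes from −0.02 to 0.12 and gave 1883 higher and 554 lower. Of 18 other settings, the calls of Bmf, Rag2, Myc and Bak1 were lost in 9, 7, 2 and 1, at adjusted p up to 0.123, 0.0848, 0.0587 and 0.073. Of 89 called genes of the naming rule, 57 lost their call in at least 1 setting and 7 in more than 50%, among them Bcl2l2, E2f1 and Rrm2. The early B, cell cycle and pro-survival lists lost theirs in 12, 8 and 3 of 17 settings, at adjusted p up to 0.23, 0.25 and 0.108. Plasma cell markers gained a call in 2 (adjusted p down to 0.00612) and interferon genes in 1 (0.0211).

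**Figure D3:**
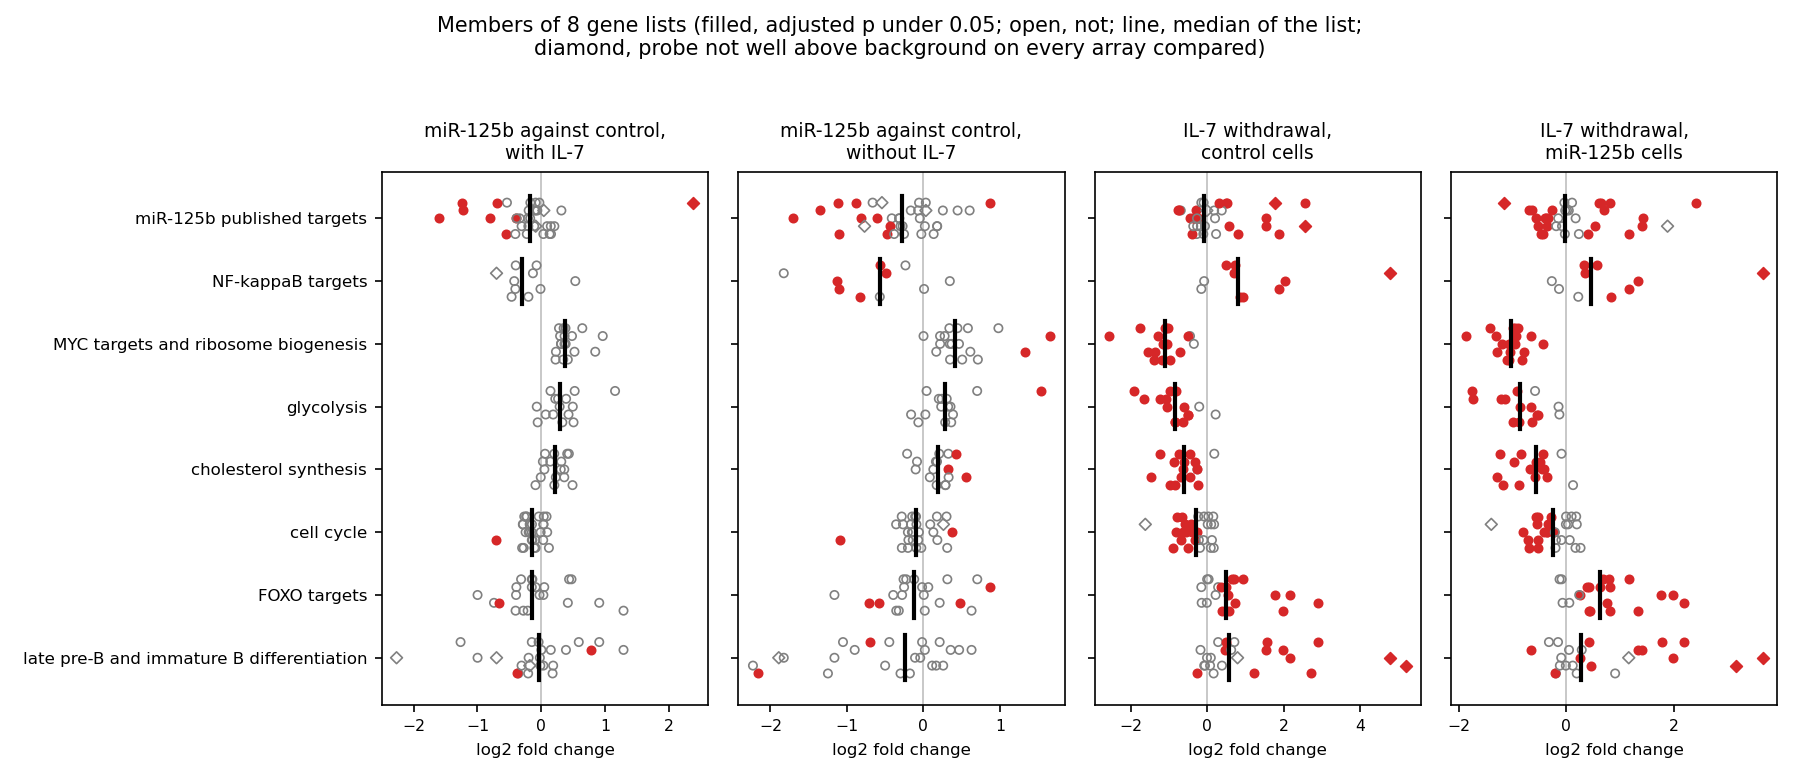
Log2 fold change of each measured member of 8 gene lists in 4 comparisons; filled marks passed an adjusted p under 0.05, diamonds are probes not well above background on every array compared, whose fold is not measured, and lines are medians. All 18 members of the list of MYC targets and ribosome biogenesis fell on withdrawal in miR-125b cells, and 12 to 14 members of the glycolysis and cholesterol lists fell on withdrawal in each cell type.

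How control cells respond to 24 h without IL-7 was asked next; all values below also carry the difference between slides. Myc fell by 2.11 (SE 0.25, adjusted p = 0.00199) and the cyclin gene Ccnd3 by −0.80 (SE 0.08), while the recombinase genes Rag1 and Rag2 rose by 2.89 (SE 0.28) and 1.98 (SE 0.26). Irf4, a transcription factor of light chain recombination, rose by 1.53 (SE 0.12), the Src family kinase gene Blk by 2.62 (SE 0.18) and Bmf by 2.55 (SE 0.20, adjusted p = 0.00122). Bbc3 (0.80), Prdm1 (0.56) and Jun (1.505) rose, and Bak1 (−0.30), Map3k11 (−0.39) and Trp53 (−0.78) fell. Il7r (−0.15), Bcl2l11 (−0.01), Cish (0.41), Bcl2 (0.44, adjusted p = 0.0534) and Lat (−0.23) did not pass, and Blnk rose by 0.24 but was −0.09 under scaling to the median.

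In control cells 11204 of 20677 genes were called, 4139 higher and 7065 lower without IL-7. Of these, 3176 changed by at least 2-fold, 1675 higher and 1501 lower. The highest were T-cell coreceptor gene Cd8a (at least 86.5-fold), Eps8 (at least 49.5-fold), Trim12a (at least 41.1-fold), Ltbp2 (at least 32.2-fold), Cnrip1 (at least 21.8-fold), Gnpda2 (at least 20.9-fold), Zfp882 (at least 13.3-fold), Pramel39 (at least 12.6-fold) and Parp8 (at least 11.9-fold), whose probes were not well above background with IL-7, and Ggh (5.38, or 2.18 to 6.39 under other settings), seen on 1 of 2 arrays with IL-7. The lowest measured on all arrays were Insm1 (−3.89, SE 0.34), Serpinb9c (−3.11, SE 0.54) and Tmem98 (−2.95, SE 0.15). Without IL-7, Srxn1 was at least 7.12-fold lower, Ptgir at least 5.17-fold, the phosphatase gene Dusp8 at least 2.48-fold, Olfr1211 at least 2.36-fold and Inava at least 1.87-fold, and Cst7 (−3.48, or −3.88 to −2.19 under other settings) and Abhd14a (−3.46, or −3.91 to −2.05) were each seen on 1 of 2 arrays.

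Of 18 ribosome biogenesis genes 16 fell, such as Srm (−2.57) and Gnl3 (−1.76), of 15 glycolysis genes 13, such as Aldoa (−1.94) and Eno1 (−1.66), and of 16 cholesterol genes 14, such as Fdps (−1.49) and Mvd (−1.25); the rest did not pass, and 17, 13 and 14 fell when adjusted over the list alone. Their camera adjusted p were 7.77e-05, 0.00138 and 0.000527. Of 21 FOXO targets 14 rose and 0 fell, such as Rag1, Rag2 and Btg1 (1.76), and 15 when adjusted over the list alone (camera adjusted p = 8.55e-05). Of 24 late pre-B genes 11 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.000335): Cd40 was at least 27.1-fold and the B-cell antigen Ms4a1 at least 9.63-fold higher, and Cd74 rose by 2.72. Of 10 NF-kappaB targets 8 rose and 0 fell, also when adjusted over the list alone, such as Tnfaip3 (1.87), Traf1 (0.94) and Nfkb2 (0.85), and Relb by 2.04, although 1 of its 3 probes read −0.03 (camera adjusted p = 0.000527). For each of these 6 lists the adjusted p = 0.599 with an estimated correlation.

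Of 4 pro-survival BCL2 genes Bcl2l1 (0.80) and Bcl2l2 (0.68) rose (camera adjusted p = 0.0277), and 4 when adjusted over the list alone. Of 21 p53 targets 7 rose, such as Zmat3 (2.06), Trp53inp1 (1.53) and Btg2 (1.16), and 3 fell, among them Aen (−0.94) and Cdkn1a (−0.86, with probes up to 1.04), with the same counts when adjusted over the list alone (camera adjusted p = 0.0455). Their median of 0.17 became −0.16 under scaling to the median, which left the list at 0.30 relative to all genes. Both lists had an adjusted p = 0.599 with an estimated correlation. The other 12 lists did not pass, at camera adjusted p from 0.0506 for 17 STAT5 targets to 0.906 for 6 plasma cell markers. Of the STAT5 targets 7 rose, such as Il2ra (1.57), Socs3 (0.80) and Ccnd2 (at least 2.75-fold higher), and 3 fell, or 9 and 3 when adjusted over the list alone. These targets passed in 8 of 17 other settings, such as normexp (camera adjusted p = 0.00517). Of 28 cell cycle genes 14 fell, such as Mcm6 (−0.89) and Pcna (−0.81), but their median of −0.30 became 0.03 under quantile normalization. The list passed in 3 of 17 settings, such as scaling to the median (camera adjusted p = 0.0323, with −0.17 relative to all genes). Of the 34 published targets 11 rose and 8 fell, or 11 and 9 when adjusted over the list alone, with a median of −0.08 (0.22 under quantile normalization) and a mean of 0.27. They passed as higher with normexp and the deposited table (camera adjusted p = 0.0303 and 0.0466). Early B genes were split as 7 higher, such as Blk, Bach2 (1.26) and Pax5 (0.79), and 4 lower, among them Dntt (−0.48) and the surrogate light chain gene Vpreb1 (−0.64, but 0.11 under quantile normalization), pro-apoptotic BCL2 genes as 2 and 5, with Bok (−2.55) and Bid (−1.74) falling, and JNK genes as 5 and 2, each with the same counts when adjusted over the list alone. Early B genes had a median of 0.02 (−0.32 under scaling to the median, but 0.15 relative to all genes in both) and passed under quantile normalization (camera adjusted p = 0.000129).

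Markers of other cell types moved without a common direction. Of 6 T and NK markers Cd8a rose and 3 fell, among them Cd3e (−1.44), with a median of −0.32 and a mean of 0.78. Of 10 myeloid markers 3 rose, such as Fcgr3 (1.104), and Elane (−0.52) fell; of 4 erythroid markers Epor rose (0.92, but −0.03 with normexp) and Car1 (−0.80, on 1 of 2 arrays) fell. Of 6 plasma cell markers Irf4 and Prdm1 rose and 4 fell, among them Sdc1 (−1.64), with a median of −0.38 (0.01 under quantile normalization), of 2 stromal markers Col1a2 (−0.51, on 1 of 2 arrays) fell, and of 9 interferon genes 2 rose and 1 fell. Adjusted over the list alone these counts were the same.

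The count in control cells was 7241 without control replicate 1 lacking IL-7. The median of all genes was −0.13, and −0.47 under scaling to the median and −0.24 with normexp, where 2126 genes were higher and 10619 lower, and 3327 and 9816. Of 20 other settings, the calls of Blnk, Bak1, Prdm1, Ccnd3 and Trp53 were lost in 12, 9, 3, 2 and 1, at adjusted p up to 0.535, 0.606, 0.185, 0.37 and 0.0509, with Bak1 as small as −0.04 and Ccnd3 as small as −0.07. Of 110 called genes of the naming rule, 39 lost their call in at least 1 setting and 2 in more than 50%. The p53 and pro-survival lists lost theirs in 6 and 5 of 17 settings, at adjusted p up to 0.13 and 0.112. Without IL-7 the median shift of the 7 spike-in probes above 5 on the log2 scale on all arrays was −2.09 relative to the 75th percentile. Of the 7065 genes called lower, 6958 fell by less than this, so these falls are relative to the other genes of the array and not to the spike-ins.

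In miR-125b cells the response to withdrawal had the same outline. Myc fell by 1.45 (SE 0.25, adjusted p = 0.0061) and Ccnd3 by −0.67, while Rag1 (2.19, SE 0.28), Rag2 (1.33, SE 0.26), Irf4 (1.40, SE 0.12), Bmf (2.42, SE 0.20, adjusted p = 0.00167), Bbc3 (0.40), Prdm1 (0.54) and Bcl2 (0.51) rose. Bak1 fell by 0.57 (SE 0.08), Map3k11 by −0.40 and Trp53 by −0.65. Il7r (−0.07), Bcl2l11 (−0.13), Cish (−0.47), Blnk (0.16) and Lat (−0.23) did not pass.

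In miR-125b cells 10843 genes were called, 4198 higher and 6645 lower without IL-7. Of these, 2816 changed by at least 2-fold, 1720 higher and 1096 lower. Cd8a was at least 99.0-fold higher, Trim12a at least 25.0-fold, Gnpda2 at least 23.6-fold, Cnrip1 at least 21.5-fold, Parp8 at least 11.9-fold, Zfp882 at least 11.5-fold, Pramel39 at least 7.96-fold and Zfp783 at least 7.66-fold, and Eps8 rose by 4.94 (SE 0.40) and Epha2, seen on 1 of 2 arrays with IL-7, by 6.02 (4.01 to 6.77 under other settings). Nr2c1 was at least 9.32-fold lower, Srxn1 at least 8.45-fold, Plekha7 at least 6.18-fold, Tom1l1 at least 5.40-fold, Ltb4r2 at least 3.87-fold, Dusp8 at least 3.34-fold and Elovl7 at least 2.94-fold, and Cst7 (−3.94), Insm1 (−3.83) and Bok (−3.08) fell on all arrays. Across genes the withdrawal responses of both cell types correlated at r = 0.889, and 9159 of 9174 genes called in both moved the same way. Both responses are taken between the same 2 slides, so a difference between slides would enter both alike and raise this agreement.

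All 18 ribosome biogenesis genes fell in miR-125b cells, also when adjusted over the list alone (camera adjusted p = 5.64e-05), such as Srm (−1.87) and Npm1 (−1.31). So did 12 of 15 glycolysis genes (camera adjusted p = 0.000527), such as Aldoa (−1.75), and 14 of 16 cholesterol genes (camera adjusted p = 0.000286), such as Fdps (−1.29), with the same counts when adjusted over the list alone. Of 21 FOXO targets 16 rose, such as Btg1 (1.76) and Klf2 (1.17), and 17 when adjusted over the list alone (camera adjusted p = 3.54e-05). Of 10 NF-kappaB targets 7 rose, also when adjusted over the list alone, such as Relb (1.34), Tnfaip3 (1.17) and Birc3 (0.57) (camera adjusted p = 0.00856). Each of these had an adjusted p = 0.599 with an estimated correlation. Of 24 late pre-B genes 10 rose, such as Il2ra (1.78) and Ms4a1 (at least 2.24-fold), and 2 fell, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0162; adjusted p = 0.623 with an estimated correlation, fry adjusted p = 0.0727).

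The other 14 lists did not pass in miR-125b cells, at camera adjusted p from 0.059 for p53 targets to 0.995 for stromal markers. Of 21 p53 targets 8 rose and 3 fell, with a median of 0.09 (−0.16 under scaling to the median, but 0.20 relative to all genes in both), and of 28 cell cycle genes 14 fell, such as Pcna (−0.81) and Ccne1 (−0.71), while their median of −0.26 became 0.10 under quantile normalization. Of 34 published targets 10 rose and 12 fell, with a median of −0.02 (0.11 under quantile normalization) and a mean of 0.17, and Lifr was at least 1.51-fold lower. Of 15 JNK genes 6 rose, such as Dusp16 (1.09) and Jun (1.08), and 2 fell; of 4 pro-survival genes 3 rose, and of 10 pro-apoptotic genes 2 rose and 6 fell. Early B genes rose and fell 6 to 6, with a median of −0.02 and a mean of 0.19, and passed under quantile normalization with a median of 0.38 (camera adjusted p = 0.000162). STAT5 targets rose and fell 6 to 4, interferon genes 3 to 2, plasma cell markers 2 to 4 and erythroid markers 1 to 1. Of T and NK markers Cd8a rose and Cd3e (−1.52) fell, with a median of −0.13 and a mean of 0.99, 3 myeloid markers rose and 1 stromal marker fell. Adjusted over the list alone, 1 cell cycle gene rose and the other counts of these lists were the same. The count was 7175 without miR-125b replicate 1 lacking IL-7, and scaling to the median moved the median of all genes from −0.11 to −0.36 and gave 2460 higher and 8903 lower, while normexp, with a median of −0.24, gave 3278 and 9836. Of 20 other settings, the calls of Bcl2, Bbc3, Prdm1, Trp53 and Ccnd3 were lost in 12, 6, 4, 3 and 2, at adjusted p up to 0.253, 0.41, 0.108, 0.0716 and 0.905, with Bcl2 as small as 0.23, Bbc3 as small as 0.16 and Ccnd3 as small as −0.01. Of 17 settings, p53 targets gained a call in 6, cell cycle and early B genes in 3 each and published targets and pro-survival genes in 1 each, at adjusted p down to 0.00282, 0.0311, 0.000144, 0.0303 and 0.0482. Of 106 called genes of the naming rule, 37 lost their call in at least 1 setting and 4 in more than 50%. Of the 6645 genes called lower, 6548 fell by less than the median of the 7 brighter spike-in probes.

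Whether miR-125b alters the response to withdrawal was tested as the difference of both responses, in which an additive difference between slides cancels. No gene passed (0 of 20677 with limma; lowest adjusted p = 0.149; 1219 genes, or 5.9%, at an unadjusted p under 0.05), so that no gene is shown to respond differently. Among the lowest p, none of which passed, were those of Tmem139 (adjusted p = 0.149), Slc39a5 and Pdzk1, whose probes were not well above background in several groups, and of St3gal6 (1.36, SE 0.13) and Vat1 (1.21, SE 0.14), both at adjusted p = 0.332. St3gal6 fell by 1.65 in control and by 0.29 in miR-125b cells. For Map3k11 the difference was −0.01 (SE 0.10), for Bak1 −0.27 (SE 0.12), for Bmf −0.13 (SE 0.28), for Bbc3 −0.40 (SE 0.13), for Rag1 −0.69 (SE 0.40), for Rag2 −0.65 (SE 0.37) and for Myc 0.67 (SE 0.36). For Irf4 (−0.13), Prdm1 (−0.02), Trp53 (0.14), Bcl2 (0.08), Bcl2l11 (−0.12), Il7r (0.08), Ccnd3 (0.13), Cish (−0.88), Blnk (−0.09) and Lat (0.01) it did not pass either.

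As lists, the 10 NF-kappaB targets rose less on withdrawal in miR-125b than in control cells (camera adjusted p = 5.64e-05; adjusted p = 0.599 with an estimated correlation, fry adjusted p = 0.0562), with 0 members passing and 2 lower when adjusted over the list alone. Relb (−0.70), Tnfaip3 (−0.69) and Nfkb2 (−0.63) had the lowest differences of those measured well above background in all groups. The 24 late pre-B genes were lower as well (camera adjusted p = 0.00495; adjusted p = 0.599 with an estimated correlation, fry adjusted p = 0.423), with 0 members passing, also when adjusted over the list alone; Cd74 (−1.81) was among them. This call was lost in 3 of 17 settings, at adjusted p = 0.108 with no filter on dim probes and 0.252 and 0.41 without replicate 1 of control or miR-125b cells with IL-7. The other 18 lists did not pass, at camera adjusted p from 0.137 for STAT5 targets to 0.965 for FOXO targets. Of 17 settings, FOXO targets gained a call in 2 and ribosome biogenesis, STAT5 targets, cell cycle and interferon genes in 1 each, at adjusted p down to 0.0112, 0.00958, 0.0489, 0.0434 and 0.0298. The count of genes was 3 without miR-125b replicate 1 lacking IL-7, 1 without miR-125b replicate 1 with IL-7, 5 with normexp and 2 with a mean-variance trend.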

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

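Leaving out arrays and estimating the correlation were planned for all lists; their use to weigh the result for NF-kappaB targets, and the test of the spike-in probes, were chosen after the result was seen. A planned test of the difference between the withdrawal responses of miR-125b and control cells drew attention to 2 gene lists, whose camera test passed at the preset correlation. Both hold Cd40, whose probe was not well above background in control cells with IL-7, so they are not fully separate results. Neither was tested without it. Late pre-B genes were lower in the difference at camera adjusted p = 0.00495 (adjusted p = 0.599 with an estimated correlation; limma's fry, which does not compare with other genes, adjusted p = 0.423). The list did not pass without replicate 1 of control or miR-125b cells with IL-7 or with no filter on dim probes (camera adjusted p = 0.108), so a single array as the source stays open. A correlation between the list's genes above the preset value, estimated at 0.337, stays open as well.

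NF-kappaB targets were lower in the same difference at camera adjusted p = 5.64e-05, with a median of −0.27 and fry adjusted p = 0.0562, and 0 of 10 members passed alone. A single array as the source is argued against: the highest adjusted p without each array in turn was 0.00282. The planned test without the Bcl2a1 genes, whose sequences are alike, was void, since none of them is among the 10 members measured, and its value of 5.64e-05 is that of the full list. A correlation between the list's genes above the preset value, estimated at 0.268, stays open. The camera adjusted p of 0.599 with this estimate does not decide it, since that form of the test has only 4 residual degrees of freedom. A change of NF-kappaB activity by miR-125b, the biological difference in the design, was not tested and stays open as well.

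Many genes, 12156 in the split below, differ between the arrays with and without IL-7, which are also 2 slides with their own scans. Spike-in probes were compared only if above 5 on the log2 scale on all arrays, which left 7. Their log2 shift between the slides, before scaling, ranged from −1.45 to −0.79 with an SD of 0.225. The SD over genes was 0.816, or 0.563 for the brighter genes, and the 75th percentile differed by 0.93. Dimmer spike-ins moved otherwise. The log2 signal of E1A_r60_3 was 1.40 to 1.59 with IL-7 and 2.72 to 3.11 without. That of E1A_r60_a104 was 1.62 to 2.34 and 3.02 to 3.91, and that of E1A_r60_a107 3.73 to 4.00 and 3.52 to 3.99. Relative to the 75th percentile the median shift of the 7 brighter spike-ins was −2.09. On withdrawal in control and miR-125b cells, 6958 and 6548 of the genes called lower fell by less. The direction of these falls would therefore turn on the scale of these 7 spike-ins. The spread of the 7 brighter spike-ins lies below that of the genes but above the tenth of it that was set to exclude the slides. The dimmer ones did not share their shift, so the shift between slides varied with the signal level. The order of the spreads was found for bright spike-ins only, and the probes are few. Withdrawal and slide cannot be told apart, because the design places them on the same arrays.

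Of the 34 splits of the arrays into 4 and 4 that were tested, 1, the real one, called as many as 3269 genes. These are the genes of miR-125b against control averaged over IL-7 conditions, and the highest other split called 10. Only 18 of the splits, the real one included, had its form of 2 and 2 arrays of each slide. They are too few to reach a share under 0.05, so chance is not excluded as the source of this count. Position on the slide, which follows the vector on both slides, was not tested as the source and stays open. The log2 signal of the dim spike-in E1A_r60_a104 was 2.34 and 2.31 on control against 1.62 and 1.68 on miR-125b arrays with IL-7. Without IL-7 it was 3.62 and 3.91 against 3.02 and 3.06. E1A_r60_3 was also lower on the miR-125b arrays of each slide, and E1A_r60_a107 on those with IL-7. For the 7 brighter spike-ins the values of both vectors overlapped on each slide. Differences of dim genes between vectors may thus carry a technical offset. In the 18 splits with 2 and 2 arrays of each slide the highest count other than the real one was 2. Of the same 34 splits, 3, the real one among them, put as many as 8 lists past the threshold, so chance is not excluded for the number of lists. The split between slides, fitted without a slide term, called 12156 genes.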

How the results depend on the processing

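All settings of this part were fixed before the data were examined, and none was chosen after the result was seen. Of 8959 values of named genes under the alternatives, 7520 kept their side of the threshold, 1382 became weaker, 35 stronger and 22 reversed. Those among the 7520 that were called also kept their direction. For genes that passed in neither fit a change of sign was not counted. Of 629 values of the 37 list tests that passed, 568 kept their direction and call and 61 became weaker. Of 1405 values of the 83 that did not pass, 46 passed, in 21 tests, and of 133 counts 82 moved by less than 1.5 times. Where a value moved, the cause was not tested, apart from the stricter threshold, which calls fewer genes by its construction. Map3k11 stayed lower throughout, at adjusted p up to 0.021 in the average, 0.169 with IL-7 and 0.0813 without it. With 2 arrays per group a left-out array leaves 1 sample in its group, whose variation is assumed to be that of the other groups.

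For miR-125b with IL-7 the count was 220 under median scaling, 1 with no filter on dim probes, 915 with probes above background on all arrays, 0 with only the 4 arrays compared (limma; 3060 genes at an unadjusted p under 0.05), 1558 with a mean-variance trend and robust eBayes, 187 at 2-fold or more, and from 0 to 140 without 1 array (100, 26 and 28 among these). Without IL-7 it was 2663 with normexp, 2077 with quantile normalization, 858 under median scaling, 606 with no filter on dim probes (163 higher and 443 lower), 2066 with the deposited table, 496 with only the 4 arrays compared, 2693 with a mean-variance trend, 339 at 2-fold or more, and from 3 to 1138 without 1 array (875, 36, 114 and 30 among these). The average gave 1404 with no filter, 370 at 2-fold or more, and from 995 to 2608 without 1 array (1707, 2018, 1487, 1173 and 1279 among these). Withdrawal gave 3176 and 2816 at 2-fold or more in control and miR-125b cells, and from 7241 to 11080 and from 7175 to 10705 without 1 array. The difference gave 5 with normexp, 1 each with quantile normalization, median scaling and the deposited table, 2 with a mean-variance trend, and from 0 to 3 without 1 array (1 without miR-125b replicate 1 with IL-7). Of 120 list tests 37 passed, 0 with an estimated correlation and from 30 to 41 without 1 array. Early B genes lost their call in most alternatives, and the medians of some lists near 0 changed sign under scaling to the median, with the shift of all genes.

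Replicate numbers are shared by the groups but were not taken to pair arrays: the differences between replicates 1 and 2 correlated across genes at −0.0981 to 0.114 between groups. With a replicate block the counts were 17 with IL-7, 454 without, 2170 for the average, 10483 and 10082 for withdrawal in control and miR-125b cells and 0 for the difference (limma; 1164 genes at an unadjusted p under 0.05), and 32 lists passed. With the block by clone, of vector and number, withdrawal gave 9338 and 8897 and the difference 0 (1161 at an unadjusted p under 0.05). A slide block cannot be estimated for withdrawal, and leaves miR-125b against control and the difference as they are, since the group means already hold the slide.

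Some directions reversed. With normexp on withdrawal in control cells these were Cd14 (−0.36), Epor (−0.0257) and Lifr (−0.28), and in miR-125b cells Ccnd2 (−0.35), Cd14 (−0.34), Flt3 (−0.0672), Ifit3 (−0.27), Oasl1 (−0.0196) and Traf1 (−0.0798). The probes of Cd14, Lifr, Ccnd2 and Oasl1 were well above background on no array of at least 1 group compared, so their values are those of the fit and not measured folds. Quantile normalization and the deposited table turned Mzb1 in control (0.13 and 0.14) and miR-125b cells (0.20 and 0.22), and Vpreb1 (0.11 and 0.11, then 0.15 and 0.14). Median scaling turned Blnk on withdrawal in control cells (−0.091), the mean of a gene's probes Cdkn1a on withdrawal in control cells (0.055) and Fdft1 for miR-125b without IL-7 (−0.13), and no filter on dim probes Lifr on withdrawal in control cells (−0.0916) and Rnf150 for miR-125b without IL-7 (0.93). Signal over background limits the genes seen: about the 47.8% to 54.8% of probes well above it on each array, with folds of dimmer ones known only as bounds. The planned test of seed sites in 3′ untranslated regions was not run.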

Other observations

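The MHC class II genes, the pairs of neighbours and the seed words below were chosen for a test after the result was seen, apart from the test of overlapping genes. H2-Aa, an alpha chain of MHC class II, rose by 1.23 on withdrawal in control cells (SE 0.27, adjusted p = 0.0124) and was −0.19 in miR-125b cells, and H2-Eb1, a beta chain, was 0.62 in control cells (adjusted p = 0.0501) and fell by 0.66 in miR-125b cells (adjusted p = 0.0432). With Cd74 (2.72 against 0.91), their invariant chain, the differences between both responses were −1.81 for Cd74, −1.42 for H2-Aa, −1.28 for H2-Eb1 and −0.65 for H2-Ab1, none of which passed (adjusted p from 0.569 to 0.629; n = 2 arrays per group).

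Several genes that changed at least 2-fold with miR-125b, averaged over IL-7 conditions, lie next to each other. Tgfb3 (4.27; probe on chromosome 12 from 87397804 to 87397863) and Ift43 (3.75; from 87503290 to 87503349) rose together, as did Septin12, Smim22 (2.25) and Rogdi (1.74), and Srm (1.31) and Masp2 (1.30), a protease gene of the complement system. Ly6d (−2.15) and Lynx1 (−1.28), of the same family of surface proteins, fell together. Among 13741 genes with a position, 294 were called at this size and formed 9 neighbouring pairs within 200 kb. Shuffled positions gave a median of 2 pairs, an upper 95% bound of 6 and a highest value of 11, and 1 of 1000 shuffles had as many as 9, so by the bound used, the highest shuffle, chance adjacency is not excluded. Overlapping transcripts or related probe sequences are argued against as the whole source. Without overlapping genes or a 15-mer shared by the probes 7 pairs remained, against an upper 95% bound of 5. This bound is less strict than the highest shuffle used for chance adjacency. What else joins these pairs was not tested, among it the insertion of a vector.

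As a hypothesis, mRNAs whose probes hold a match to the seed of miR-125b were asked to be lower in miR-125b cells. Among words of the same base composition, 0.0317 had as low a score as CTCAGGG (4 of 126) and 0.00415 as low as TCAGGGA (1 of 241), averaged over IL-7 conditions. The shares were 0.0238 and 0.00415 with IL-7 and 0.0238 and 0.0415 without it. The median log2 fold change of genes with the words was −0.0771 and −0.0782, against −0.0246 for genes without. This is consistent with repression through seed matches, but a probe of 60 bases covers only a part of each transcript, and the shift is small.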
